A study of Homo sapiens with 76 samples.

How the data were processed

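The deposited files hold read counts per gene for 76 libraries of 4 human cell lines, which the authors made with bcl2fastq 2.20, STAR and HTSeq on the GRCh38 build, per the submitters' processing notes. These raw counts are whole numbers of reads with no scaling. The notes give no versions for STAR and HTSeq, no annotation release and no strand setting. Per the labels' protocols, RNA was extracted with Trizol and column-cleaned. PolyA libraries were made with a stranded mRNA kit, and the total RNA libraries with a different stranded kit after removal of ribosomal RNA. Hypoxia lasted 24 h at 0.2% oxygen. MALAT1 was lowered transiently with an ASO or targeted by knockout, and SRSF1 was lowered stably with shRNA.

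The libraries formed 9 sets, each with 4 groups by depletion and treatment, named MCF7 MALAT1 ASO, MCF7 MALAT1 KO, MCF7 SRSF1 shRNA, HEK293T MALAT1 ASO, HEK293T SRSF1 shRNA, MCF7 MALAT1 ASO CoCl2, MDA-MB-231 MALAT1 KO, HCT116 MALAT1 ASO and MCF7 MALAT1 KO total RNA. Controls were a scramble ASO, WT cells or an empty lentiviral vector, and no control library was shared between sets. Untreated cells of the CoCl2 set carry DMSO as their treatment in the labels. All groups had 2 libraries except the total RNA groups, with 3. Every column of the files was matched to a label, and 0 columns stayed unmatched, though HEK293T columns could be matched to their group only. Replicate numbers of MDA-MB-231 are those of the sample titles, which differ from those in the file names. Nothing in the sources states that replicates were separate cultures, so the p-values measure the spread between these libraries.

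Of 60623 gene identifiers, 60295 carried a symbol and 58516 were found in GENCODE release 29, from which symbols and GRCh38 coordinates were taken. Depth in gene reads, in units of 1e+06, ran from 39.9 to 52.1 in the MCF7 ASO set, 100.8 to 123.9 in the MCF7 KO set and 39.7 to 65.8 in the MCF7 SRSF1 set. It ran from 4.7 to 5.8 and from 4.8 to 5.9 in the HEK293T MALAT1 and SRSF1 sets, 60.2 to 77.1 in the CoCl2 set, 70.1 to 90.2 in MDA-MB-231, 59.6 to 74.6 in HCT116 and 12.3 to 18.2 in total RNA. Files of the last 4 sets end with HTSeq's summary lines, which are not genes and were left out. By these lines 82.5% to 84.1% of uniquely aligned reads lay in no feature in total RNA, against 6.6% to 9.0% in the CoCl2 set, 6.2% to 7.2% in MDA-MB-231 and 10.2% to 14.5% in HCT116. Mitochondrially encoded genes took 1.56% to 10.02% of gene reads in HCT116 libraries. The variance between replicates was 1.58 to 70.23 times that of sampling, so no pair of replicates agreed within sampling noise. Intervals and floors on reads cover counting error only.

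Each set was fitted alone with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total count 15), a 4-group design and the quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene was called at adjusted p < 0.05. The contrasts were treated minus untreated in control cells, depleted minus control averaged over both conditions, and the interaction, that is the treatment response in depleted cells minus that in control cells. Fold changes are on the log2 scale with the standard error of the fit, and CPM values are means with SD over the libraries of a group. Genes of groups with 3 or fewer reads are given as reads or CPM without a fold. Where the fitted interaction of such a gene is given, its reads stand beside it and it gives no size. Joint counts over sets compared the calls with the number that independent lists would share, which takes no account of a line or way of depletion shared by sets.

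Gene lists were tested with camera of limma 3.58.1 on voom values, with an estimated correlation between genes and Benjamini-Hochberg adjustment over the lists of a contrast. The lists were HIF glycolysis, other HIF targets, cell cycle, stress response (UPR and ISR), sterol synthesis, oxidative phosphorylation, SR proteins and CLK kinases, nuclear speckle and paraspeckle, MALAT1 neighbours, estrogen response, mesenchymal and epithelial, p53 targets, interferon response, metal and oxidant response, mitochondrially encoded, ribosomal proteins, replication-dependent histones, and line markers of MCF7, MDA-MB-231, HCT116 and HEK293T. TALAM1, the antisense partner of MALAT1, was not found in the files. Core hypoxia genes were those that rose in control cells of at least 5 other hypoxia sets, never the set tested. Sets, contrasts, lists, the rule for named genes and the alternatives were fixed before the data were examined. That rule took MALAT1 and SRSF1, the 15 highest and 10 lowest genes called alike under hypoxia in every set used, and the 6 highest and lowest under CoCl2. It took the 5 highest and lowest of each depletion effect, the 10 genes called by MALAT1 depletion in most sets, the 3 highest and lowest of each interaction, and the 4 list members with the smallest p. Named genes had a mean of at least 1 CPM.

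The HEK293T counts lay on the strand opposite to the gene, as judged from antisense genes. These sets were therefore left out of named genes and of the gene lists named above, a choice made after the data were seen. The rule for genes shared by both SRSF1 sets was not applied. Core hypoxia lists and joint counts still included the HEK293T sets, except where own-strand sets are named. The number of a replicate was checked as a pair by correlating deviations from the group mean across genes. In the MCF7 SRSF1 set these correlations were 0.54 to 0.72, so its numbers pair libraries, and values with the replicate as a block are given.

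The alternatives were RLE factors, DESeq2 1.42.0 with its own filtering, no low-count filter, the replicate number as a block, a preset correlation of 0.01, a core list from at least 3 sets, and leaving out each library in turn. Added after seeing the data were counts and core lists from own-strand sets alone, the gene lists under the other settings, and the joint fit of the MCF7 ASO and KO sets. The pipeline was tested on simulated data with the depths and spread of the MCF7 ASO set (19926 genes) and the total RNA set (19947 genes), with 200 genes changed per contrast. In the MCF7 ASO set edgeR found 79.1%, 97% and 100% of hypoxia changes of 1.5, 2 and 4-fold, and 71.6%, 89.6% and 98.5% of such interactions. In total RNA it found 25.4%, 52.2% and 81.8% of hypoxia changes and 2.99%, 28.4% and 66.7% of interactions. False calls made up 4.9% to 7.57% of calls in the simulations. The changed genes all had a mean of at least 1 CPM. The real data held far more called genes, 55.8% for hypoxia and 73% for depletion in the MCF7 ASO set. Rates under such broad change were not simulated. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Splicing, isoforms and nuclear position were not analysed here, since counts per gene do not hold them.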

Results

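RNA was counted per gene in 76 libraries of MCF7, HEK293T, MDA-MB-231 and HCT116 cells. They formed 9 sets, each with control and depleted cells, untreated or treated, in 36 groups. Treatment was 24 h at 0.2% oxygen, or CoCl2, a chemical that stabilises HIF, in the remaining set. The depleted RNA was MALAT1, a nuclear long noncoding RNA of nuclear speckles, or SRSF1, a splicing factor of the SR protein family. Per its title, the series concerns RNA processing of hypoxia-responsive genes and assemblies of a noncoding RNA with a splicing factor. Each group held 2 libraries, or 3 in the total RNA set.

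Antisense oligonucleotides (ASO) lowered MALAT1 to 12.8% of control in the MCF7 hypoxia set (log2 fold change -2.96 ± 0.07 SE, n = 2 per group, adjusted p = 2.49e-16). They lowered it to 27.4% in the MCF7 CoCl2 set and to 20.3% in HCT116. In the knockout (KO) cells 2.76% remained in MCF7 polyA RNA (-5.18 ± 0.04, adjusted p = 1.13e-32), 5.38% in MCF7 total RNA and 26.9% in MDA-MB-231 (-1.89 ± 0.06, adjusted p = 1.66e-09). SRSF1 shRNA lowered SRSF1 in MCF7 to 32.1% (-1.64 ± 0.08, adjusted p = 0.000103). MALAT1 (chromosome 11, start 65497688, end 65506516, plus strand) and SRSF1 (chromosome 17, start 58003360, end 58007346, minus strand) were both measured in all 7 sets outside HEK293T.

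Low oxygen itself raised MALAT1 in MCF7 control cells, from 500 ± 23.1 to 1170 ± 34.9 CPM (reads scaled to the library's total, mean ± SD, n = 2) in the ASO set (log2 fold change 1.22 ± 0.09, adjusted p = 1.94e-09). CoCl2 raised it as well (1.18 ± 0.04, adjusted p = 3.36e-15), and so did hypoxia in total RNA (1.04 ± 0.13, adjusted p = 3.69e-06). The rise was 0.24 ± 0.04 in HCT116 (adjusted p = 1.66e-05). In MDA-MB-231 the estimate was -0.06 ± 0.08 (adjusted p = 0.611), and in the MCF7 SRSF1 set 0.22 ± 0.17 (adjusted p = 0.471). SRSF1 fell under hypoxia in MCF7 control cells, from 135 ± 2.66 to 60.9 ± 1.75 CPM in the ASO set (-1.15 ± 0.05, adjusted p = 7.37e-12), in the KO set (-1.11 ± 0.03, adjusted p = 4.68e-23) and under CoCl2 (-1.06 ± 0.05, adjusted p = 2.4e-13). In MDA-MB-231 it fell by 0.27 ± 0.08 (adjusted p = 0.0427). The SRSF1 set gave -0.10 ± 0.11 (adjusted p = 0.617), total RNA -0.11 ± 0.10 (adjusted p = 0.42) and HCT116 0.10 ± 0.06 (adjusted p = 0.142). Both values of the MCF7 SRSF1 set are from the fit without the replicate as a block, though its replicate numbers pair libraries. They do not show that hypoxia left MALAT1 or SRSF1 unchanged there. SRSF1 was also lower in MALAT1-depleted MCF7 cells, by 0.54 ± 0.04 on the log2 scale in the ASO set (adjusted p = 5.87e-10), by 0.16 ± 0.04 in the CoCl2 set (adjusted p = 0.000996), by 0.30 ± 0.02 in the KO set (adjusted p = 5.01e-14) and by 0.57 ± 0.07 in total RNA (adjusted p = 3.07e-06). The MDA-MB-231 KO lowered it by 0.33 ± 0.05 (adjusted p = 0.000372), and the ASO in HCT116 gave -0.03 ± 0.04 (adjusted p = 0.717). These depletion values average both conditions. In the MCF7 ASO set the gap was wider in normoxia (135 CPM in control, 76.3 in depleted cells) than under hypoxia (60.9 and 51.1 CPM). The MCF7 KO set had the reverse, 216 and 197 CPM in normoxia against 100 and 71.9 CPM under hypoxia. The interactions were 0.58 and -0.35.

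**Figure D1:**
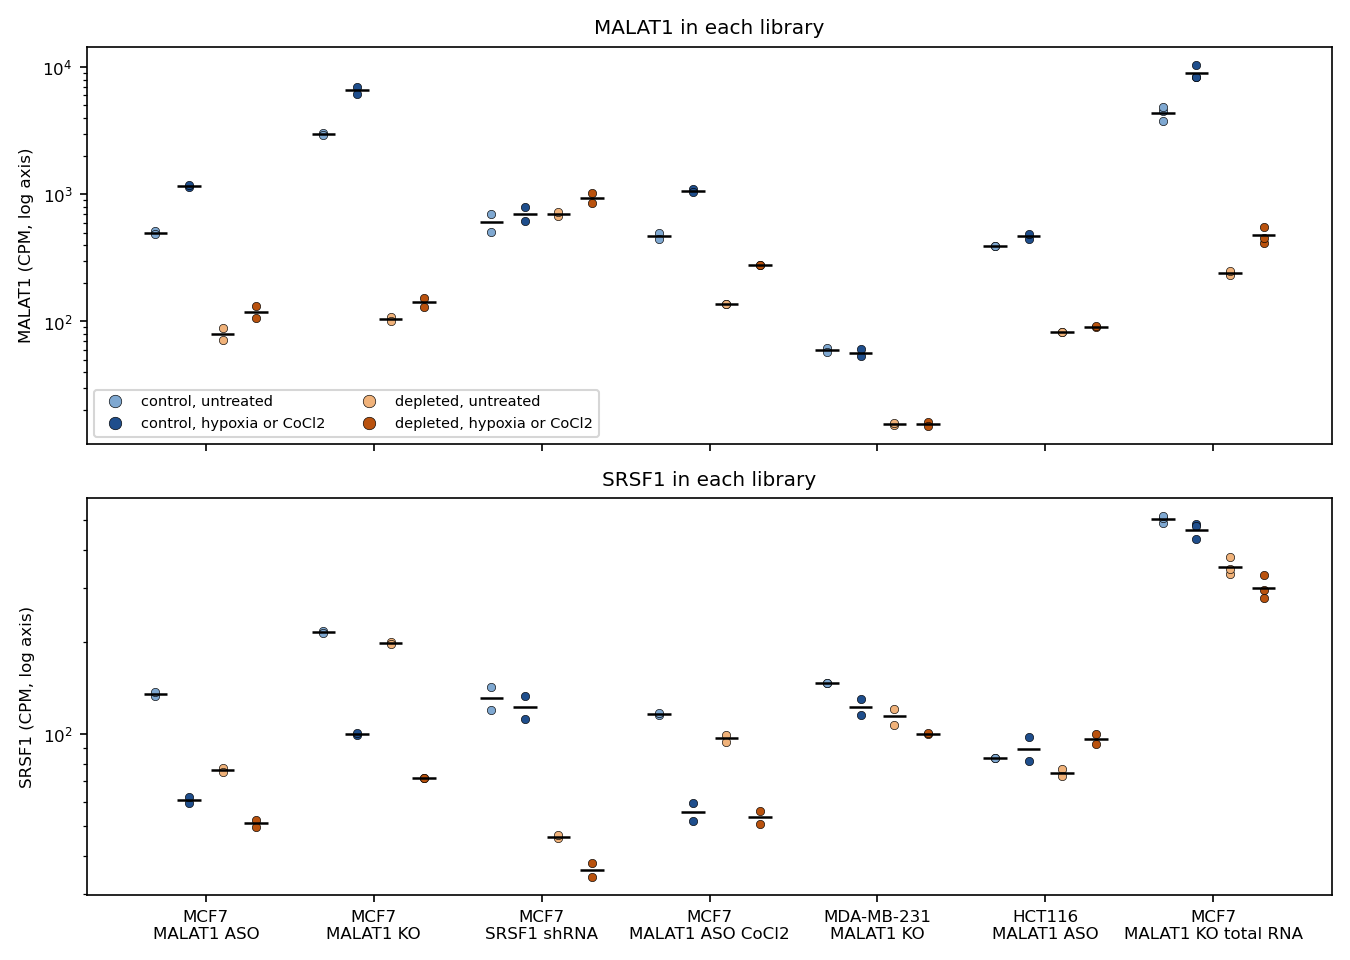
MALAT1 (upper) and SRSF1 (lower) in CPM on a log axis for each library of the 7 sets outside HEK293T, with points for libraries, bars for group means, and colours for control or depleted and untreated or treated cells. MALAT1 lies lower in depleted cells of every MALAT1 set, down to 2.76% of control in the MCF7 KO set, and SRSF1 lies lower in the SRSF1 shRNA cells.

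In the HEK293T sets the counts named after a gene were mostly not reads of that gene's own strand. Genes annotated as antisense took 43.29% to 46.76% of the reads in the HEK293T MALAT1 ASO libraries and 38.33% to 44.19% in the HEK293T SRSF1 shRNA libraries. In the other polyA sets they took 0.18% to 0.71%, and in total RNA 1.51% to 1.93%. TUBA1B, an alpha-tubulin, stood at 58.8 CPM in the HEK293T MALAT1 ASO set while TUBA1B-AS1 on the opposite strand stood at 24500 CPM, against 2380 and 3.61 CPM in the MCF7 ASO set. ACTB, cytoplasmic actin, stood at 33.3 CPM in that set against 3090 CPM in MCF7. The knockdown of MALAT1 and SRSF1 could therefore not be measured in HEK293T, and no response of a named gene is given from these sets.

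**Figure D2:**
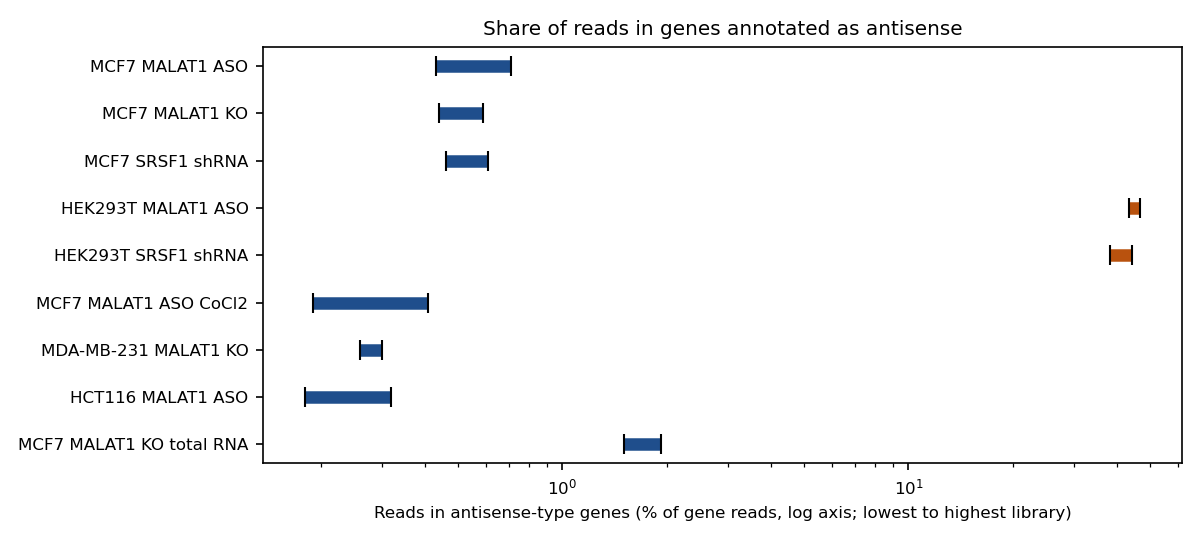
Share of gene reads in antisense-type genes, in percent on a log axis, drawn from the lowest to the highest library of each of the 9 sets. The HEK293T sets span 38.33% to 46.76%, and no library of another set exceeds 1.93%.

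HIF targets led the response of MCF7 control cells to 0.2% oxygen in the ASO set. NDRG1, a hypoxia-inducible growth regulator, rose from 44.3 ± 3.79 to 1860 ± 51.2 CPM (log2 fold change 5.40 ± 0.06, n = 2 per group, adjusted p = 3.08e-19). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 3.97 ± 0.746 to 244 ± 2.32 CPM (5.94 ± 0.10, adjusted p = 9.13e-18). CA9, a cell-surface carbonic anhydrase, went from 5 to 9872 reads. Of 21 HIF glycolysis genes all 21 rose, and of 26 other HIF targets 25 rose and 1 fell, both over all genes and adjusted over the list alone. The median log2 fold changes were 2.49 and 3.46, and each list had adjusted p = 0.017 with an estimated correlation. Sterol synthesis genes passed the same test, with 16 of 20 higher and 1 lower (median 0.72, adjusted p = 0.017 with an estimated correlation). None of these 3 lists passed without any 1 replicate of either arm.

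Mitochondrially encoded transcripts fell in these cells, all 13 of 13 both over all genes and adjusted over the list alone (median -1.97), with adjusted p = 0.0875 with an estimated correlation. Of 25 cell cycle genes 18 fell and 1 rose, or 19 and 2 adjusted over the list alone (median -0.38, adjusted p = 0.265 with an estimated correlation). The estrogen response list held 15 lower and 5 higher members of 20 by either count, such as PDZK1 (-3.72) and ESR1, the estrogen receptor (-1.07), with adjusted p = 0.241 with an estimated correlation. NEAT1, the paraspeckle RNA encoded beside MALAT1, rose by 1.52. Over all 19926 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5529 were higher and 5589 lower. The HEK293T line markers measured here numbered 4, of which 2 rose and 1 fell (median 0.18, adjusted p = 0.894 with an estimated correlation).

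In MCF7 cells with MALAT1 ASO DLGAP5, a mitotic spindle protein (chromosome 14, start 55148112, end 55191678), fell from 115 ± 2.69 to 21.7 ± 2.43 CPM in normoxia (log2 fold change over both conditions -2.82 ± 0.06, n = 2 per group, adjusted p = 6.51e-17). METTL7A, a lipid droplet-associated methyltransferase (chromosome 12, start 50923472, end 50932517), fell by 3.23 ± 0.10 on the log2 scale (adjusted p = 8.1e-15). GDF15, a stress-induced cytokine and p53 target, rose from 57.2 ± 2.61 to 670 ± 18.9 CPM in normoxia (3.13 ± 0.06 over both conditions). The noradrenaline transporter gene SLC6A2 went from 8 to 768 reads in normoxia, and the chemokine genes CXCL2 and CCL20 from 1 to 70 and from 0 to 83 reads.

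All 25 cell cycle genes fell by either count (median -1.54; BUB1 -2.03, TOP2A -2.26, AURKA -1.84), with adjusted p = 0.113 with an estimated correlation. Of 21 interferon response genes 20 rose by either count (median 1.75; IFIT2 3.37, RIGI 1.72), with adjusted p = 0.247 with an estimated correlation. Of 15 mesenchymal and epithelial genes 11 rose and 2 fell by either count (median 1.42; CCN2 5.78, SERPINE1 3.66, FN1 2.44), with adjusted p = 0.0974 with an estimated correlation. Of the 7 MDA-MB-231 line markers measured 5 rose, such as PLAU (0.0114 to 1.76 CPM in normoxia) and CAV1 (4.43), with adjusted p = 0.145 with an estimated correlation. HIF glycolysis genes fell, 20 of 21 (median -1.04), as did 19 of 20 oxidative phosphorylation genes (median -0.73), each with adjusted p = 0.0974 with an estimated correlation, the counts adjusted over the list alone being the same. In total 7334 genes were higher and 7212 lower. No list of this depletion effect passed the test with an estimated correlation.

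The hypoxia response of HIF targets was smaller in MALAT1 ASO cells than in scramble ASO cells. ADM, the vasodilator peptide adrenomedullin (chromosome 11, start 10304680, end 10307397), rose from 0.289 ± 0.172 to 35.0 ± 2.2 CPM in scramble cells and from 3.65 ± 0.3 to 18.4 ± 1.05 CPM in ASO cells (interaction -4.56 ± 0.26, adjusted p = 2.92e-09). HOXA13, a homeobox transcription factor, also had a smaller rise in ASO cells (-5.15 ± 0.63, adjusted p = 1.38e-05), though with only 4 reads in scramble normoxia. For SGK1, a serum- and glucocorticoid-induced kinase, the interaction was 3.26 ± 0.40 (adjusted p = 1.44e-05). For the chemokine gene CXCL1 it was 3.78 ± 0.96 (adjusted p = 0.00739), with 10 reads in scramble normoxia and 4 in scramble hypoxia. Among HIF glycolysis genes 20 of 21 had a lower interaction by either count (median -0.75, adjusted p = 0.0315 with an estimated correlation; PFKFB4 -1.51, ENO2 -1.40). Among other HIF targets 24 of 26 were lower and none higher, or 25 and 1 adjusted over the list alone (median -1.22, adjusted p = 0.0297 with an estimated correlation; P4HA2 -1.79).

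The interaction called 4970 genes in this set, 1902 with a higher and 3068 with a lower value. The higher share was 38.3%, and DESeq2 put it at 48%. MALAT1's own rise was smaller in ASO cells (interaction -0.64 ± 0.12, adjusted p = 0.00103). SRSF1's fall was smaller there too (0.58, adjusted p = 3.06e-05), ending at 51.1 ± 1.88 CPM from 76.3 ± 1.44 CPM. Neither HIF list of this interaction passed with the replicate as a block or without any 1 replicate of either arm.

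MCF7 cells of the KO set, wild type (WT) for MALAT1, likewise raised HIF targets at 0.2% oxygen. NDRG1 rose from 46.6 ± 0.346 to 914 ± 14.2 CPM (log2 fold change 4.29 ± 0.03, n = 2 per group, adjusted p = 1.27e-33), and BNIP3, a mitophagy receptor, rose by 3.92 ± 0.03. All 21 HIF glycolysis genes rose by either count (median 2.13, adjusted p = 0.148 with an estimated correlation). Of 26 other HIF targets 25 rose and 1 fell by either count (median 3.13, adjusted p = 0.0987 with an estimated correlation). Of 25 cell cycle genes 22 fell and 2 rose (median -0.60, adjusted p = 0.256 with an estimated correlation). Over 20820 genes tested, 7324 were higher and 7085 lower. No list passed here with an estimated correlation.

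Interferon-induced genes were far higher in MALAT1 KO than in WT MCF7 cells. IFI27 (chromosome 14, start 94104836, end 94116698) rose from 0.768 ± 0.205 to 229 ± 37.0 CPM in normoxia (log2 fold change 8.33 ± 0.09, n = 2 per group, adjusted p = 3.97e-30), and XAF1, IFI44, OAS2 and IFI6 rose by 6.51 to 8.66. All 21 interferon response genes rose by either count (median 3.80), with adjusted p = 0.333 with an estimated correlation. FLG, the skin barrier protein filaggrin, went from 2667 reads in WT normoxia to 2 in KO normoxia. SLC6A14, an amino acid transporter (chromosome X, start 116436622, end 116461458), fell from 12.3 ± 0.778 to 0.142 CPM (-6.85 ± 0.10, adjusted p = 2.46e-27). Of 20 sterol synthesis genes 19 fell by either count (median -0.81, adjusted p = 0.223 with an estimated correlation; FDFT1 -1.74), and all 17 histone genes measured fell (median -0.73, adjusted p = 0.333 with an estimated correlation). In total 6870 genes were higher and 7083 lower.

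In KO cells 6 lists had an interaction that passed, though none of them did with RLE factors, with the replicate as a block or without any 1 replicate of either arm. Of 26 other HIF targets 18 had a higher and 3 a lower interaction, or 19 and 3 adjusted over the list alone (median 0.60, adjusted p = 0.0488 with an estimated correlation). All 13 mitochondrially encoded genes were lower by either count (median -1.07), as were the mitochondrial transfer RNAs MT-TA (-4.70 ± 0.40, adjusted p = 4.44e-10), MT-TP (-3.90 ± 0.18, adjusted p = 5.86e-15) and MT-TT (-3.47 ± 0.23, adjusted p = 3.51e-12). Nuclear speckle and paraspeckle genes (11 higher, 1 lower of 18, median 0.23) and p53 targets (15 higher, 2 lower of 17, median 0.29) were higher. Estrogen response genes (1 higher, 17 lower of 20, or 19 lower adjusted over the list alone, median -0.34) and MCF7 line markers (2 higher, 7 lower of 9, median -0.57) were lower. Each of these lists had adjusted p = 0.0488 with an estimated correlation. HIF glycolysis genes, 17 higher and 3 lower of 21 by either count (median 0.41), did not pass (adjusted p = 0.0753 with an estimated correlation).

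The interaction called 8302 genes in the KO set, 4321 higher and 3981 lower. LYPD1 fell from 3.98 to 1.37 CPM in WT cells under hypoxia and stood at 0.323 and 0.641 CPM in KO cells (interaction 2.53 ± 0.25, adjusted p = 6.85e-09). HOXA13 went from 24 to 915 reads in WT and from 3 to 770 reads in KO cells (adjusted p of the interaction = 0.00217). MALAT1 itself had a smaller rise (-0.72 ± 0.07, adjusted p = 4.82e-09), and SRSF1 a larger fall (-0.35, adjusted p = 1.77e-08). In total RNA neither interaction was called, with -0.06 ± 0.18 for MALAT1 (adjusted p = 0.922) and -0.11 ± 0.14 for SRSF1 (adjusted p = 0.79). Simulations of that set found few interactions.

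Total RNA of MCF7 WT and KO cells, with 3 libraries per group, also held higher HIF targets under hypoxia. PDK1, the kinase that inhibits pyruvate dehydrogenase, rose from 47.4 ± 3.72 to 735 ± 25.9 CPM in WT cells (log2 fold change 3.95 ± 0.13, n = 3 per group, adjusted p = 8.4e-15). CA9 went from 0 to 637 reads. All 21 HIF glycolysis genes rose (median 2.43, adjusted p = 0.00822 with an estimated correlation), as did 25 of 26 other HIF targets (median 2.92, adjusted p = 0.00478 with an estimated correlation), by either count. Sterol synthesis (13 higher of 19, median 0.67, adjusted p = 0.0459 with an estimated correlation) and p53 targets (10 higher and 1 lower of 17, or 12 and 2 adjusted over the list alone, median 0.87, adjusted p = 0.0192 with an estimated correlation) passed as well. Sterol synthesis did not pass with the replicate as a block or without WT replicate 1 or KO replicates 1 or 2, nor p53 targets without KO replicates 1 or 2. Of 19947 genes tested 3346 were higher and 3372 lower.

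In total RNA the KO called 2445 genes higher and 2837 lower, with 32.8% of 1.5-fold depletion changes found in simulations of this depth. Interferon response genes rose, 16 of 20 with none lower, or 16 and 1 adjusted over the list alone (median 2.30, adjusted p = 0.0219 with an estimated correlation). XAF1, an interferon-induced gene, went from 15 to 482 reads in normoxia (n = 3 per group, adjusted p = 3.28e-11). Stress response genes fell, 9 of 18 with 2 higher, or 10 and 2 adjusted over the list alone (median -0.71, adjusted p = 0.0219 with an estimated correlation). The interferon list did not pass without WT replicate 1 or KO replicate 2, nor the stress response list with the replicate as a block or without KO replicate 2. FLG went from 200 reads in WT normoxia to 0 in KO normoxia and PRRG1, a vitamin K-dependent membrane protein gene, from 680 to 0. OR7E10P and OR7E15P, pseudogenes whose reads cannot be placed with certainty, went from 679 and 70 reads to 0.

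The interaction in total RNA called 65 genes, 22 higher and 43 lower. PGM1, phosphoglucomutase, rose from 3.44 to 16.9 CPM in WT and from a lower level of 0.232 CPM in KO cells (interaction 3.19 ± 0.54, n = 3 per group, adjusted p = 0.0103). DKK1, a secreted WNT inhibitor, fell from 93.2 ± 38.4 to 19.5 CPM in WT cells and stood at 183 and 156 CPM in KO cells (2.03 ± 0.41, adjusted p = 0.0342). Replicates of KO hypoxia agreed least in this set, with a variance of 70.23 times that of sampling between replicates 1 and 2, 27.44 between 2 and 3 and 18.91 between 1 and 3, against 4.97 to 10.53 in the other groups. Mitochondrially encoded genes took 9.02%, 18.38% and 12.1% of the gene reads of these 3 libraries. The depletion count of 5282 was 6688 without KO hypoxia replicate 2 and 4271 to 5154 without any other library. The interaction count depended on single libraries, with 1656 genes without KO hypoxia replicate 2, 192 without KO hypoxia replicate 1 and 110 without KO normoxia replicate 3. It was 17 to 34 without any other library, 296 with DESeq2 and 445 with no low-count filter, where 63.6% were higher.

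SRSF1 shRNA in MCF7 raised DCHS1, an atypical cadherin gene (chromosome 11, start 6621323, end 6655854), from 0.0497 to 5.78 ± 1.49 CPM in normoxia (log2 fold change 6.38 ± 0.39, n = 2 per group, adjusted p = 0.000105). POU2F2, a lymphoid transcription factor, rose from 0.688 ± 0.0651 to 6.89 ± 0.268 CPM (3.24 ± 0.12, adjusted p = 3.7e-05), and SELENOP, a plasma selenium carrier, by 3.11 ± 0.22 (adjusted p = 0.000129). LRP2, the endocytic receptor megalin (chromosome 2, start 169127109, end 169362685), fell from 9.93 ± 0.647 to 1.36 ± 0.208 CPM (-2.55 ± 0.15, adjusted p = 0.000104), and ALDH1A3, a retinal dehydrogenase, by 2.06 ± 0.15 (adjusted p = 0.000129). Replication-dependent histone genes rose, 16 of 17 by either count (median 1.24; H2BC21 1.62), with adjusted p = 0.575 with an estimated correlation. Of 25 cell cycle genes 16 fell, or 17 adjusted over the list alone (median -0.38; E2F1 -0.83, MCM5 -0.69), with adjusted p = 0.899 with an estimated correlation.

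With SRSF1 shRNA SRSF7 fell by 0.78 and SRSF2 by 0.77 on the log2 scale. In the list of SR proteins and CLK kinases 8 of 17 fell and 2 rose by either count (median -0.16), with adjusted p = 0.899 with an estimated correlation. Of 18652 genes tested 3645 were higher and 4099 lower with the shRNA. The replicate numbers of this set paired libraries across groups, and a fit with the replicate as a block called 10845 genes. With that block the histone, cell cycle and SR protein lists each had adjusted p = 0.471 by camera. Values given for single genes of this set are from the fit without the block.

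Hypoxia in the empty-vector cells of the SRSF1 set raised PFKFB4, a regulator of glycolytic flux, from 9.8 ± 0.231 to 150 ± 8.57 CPM (log2 fold change 3.93 ± 0.11, n = 2 per group, adjusted p = 2.88e-06). BNIP3 rose from 93.7 ± 9.62 to 847 ± 4.88 CPM (3.18 ± 0.09, adjusted p = 2.88e-06). HIF glycolysis genes rose, 20 of 21 by either count, as did 25 of 26 other HIF targets, with 1 lower adjusted over the list alone (median 1.93). Each had adjusted p = 0.128 with an estimated correlation, and 0.242 with the replicate as a block. The cell cycle, stress response and SR protein medians of 0.01, 0.01 and 0.02 changed sign under other scalings.

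In total 1052 genes were higher and 846 lower, 55.4% higher, against 43.9% with DESeq2 and 49.1% with RLE factors. The count of 1898 was 6166 with the replicate as a block, 3142 with no low-count filter, and 421 without empty-vector hypoxia replicate 1, 486 and 659 without empty-vector normoxia replicates 1 and 2, and 845 without empty-vector hypoxia replicate 2. Without the replicate block edgeR called no gene's hypoxia response different in SRSF1 shRNA cells, with 953 of 18652 at unadjusted p < 0.05. As the replicate numbers pair libraries here, this fit does not show that no response differed. DESeq2 called 3, edgeR with no low-count filter 61, and edgeR with the replicate block 414.

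HEK293T genes, read on the opposite strand, are given here only by number, and elsewhere only in joint counts over sets and in core hypoxia lists. In the HEK293T MALAT1 ASO set edgeR called 5927 of 14707 genes for hypoxia, 4268 for the ASO and 2207 for the interaction. The HEK293T SRSF1 shRNA set had 5182 of 14172 for hypoxia, 7036 for the shRNA and 2450 for the interaction. DESeq2 called 3776, 2641 and 1315 in the MALAT1 ASO set, and 3312 for hypoxia and 1480 for the interaction in the SRSF1 shRNA set.

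CoCl2 in MCF7 scramble ASO cells raised oxidant and metal defence genes together with HIF targets. HMOX1, heme oxygenase (chromosome 22, start 35380361, end 35394214), rose from 28.8 ± 0.591 to 3280 ± 159 CPM (log2 fold change 6.83 ± 0.05, n = 2 per group, adjusted p = 1.44e-24). ADM rose from 0.73 ± 0.101 to 128 ± 8.68 CPM (7.45 ± 0.08, adjusted p = 2.07e-22), and the cytokine gene TNF from 0.121 CPM (6.93 ± 0.25, adjusted p = 3.8e-15). IGFBP3, a binding protein of insulin-like growth factors, rose by 6.54 ± 0.10. CHRM1, a muscarinic acetylcholine receptor, fell from 4.11 to 0.109 CPM (-5.21 ± 0.25). All 10 metal and oxidant response genes measured rose by either count (median 2.32; GCLM 2.63, TXNRD1 2.51, NQO1 1.46), with adjusted p = 0.206 with an estimated correlation.

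All 21 HIF glycolysis genes rose under CoCl2 (median 2.33), and 25 of 26 other HIF targets (median 2.65), each with adjusted p = 0.214 with an estimated correlation. Of 18 stress response genes 16 rose and 2 fell (median 0.93; SLC7A11, the cystine transporter, 3.19), with adjusted p = 0.137 with an estimated correlation. Of 18 speckle and paraspeckle genes 15 rose and 1 fell (median 0.45; NEAT1 3.34), with adjusted p = 0.214 with an estimated correlation. All 13 mitochondrially encoded genes rose (median 0.71, adjusted p = 0.278 with an estimated correlation), where hypoxia gave medians from -2.56 to -0.05 in the other sets. Adjusted over the list alone, 2 speckle and paraspeckle genes fell and the other counts were the same. Of 18634 genes tested 6631 were higher and 7336 lower, and no list passed with an estimated correlation.

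MALAT1 ASO in the CoCl2 set raised A2M, a protease inhibitor of plasma, from 0.157 to 2.63 CPM without CoCl2 (log2 fold change 3.75 ± 0.19, n = 2 per group, adjusted p = 3.44e-11). ZNF350-AS1 rose from 0.27 to 15.9 ± 1.44 CPM (6.31 ± 0.10, adjusted p = 8.35e-19), though reads of an antisense gene cannot be placed with certainty. RAB44, a RAB-family GTPase gene, fell from 3.02 to 0.692 CPM (-1.99 ± 0.14, adjusted p = 1.33e-09). Of 21 interferon response genes 19 rose by either count (median 1.02), and of 25 cell cycle genes 24 fell (median -0.25), each with adjusted p = 0.259 with an estimated correlation. The other HIF targets had a median of -0.01, whose sign changed with no low-count filter. The effect called 4550 genes higher and 4420 lower, 50.7% higher against 38.6% with DESeq2 and 42% with RLE factors.

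The CoCl2 response of HIF targets was smaller in MALAT1 ASO cells, with 18 of 21 HIF glycolysis genes (median -0.36) and 23 of 26 other HIF targets (median -0.66; ADM -2.40) lower and 1 of the latter higher. Both had adjusted p = 0.14 with an estimated correlation, and adjusted over the list alone 18 and 24 were lower. KRT16, a stress keratin, rose from 0.399 to 16.1 CPM in scramble cells and from 3.43 to 16.8 CPM in ASO cells (interaction -3.04 ± 0.17, n = 2 per group, adjusted p = 2.67e-09). TNF's interaction was -2.56 ± 0.50 (adjusted p = 0.000922). In total 2204 genes were higher and 2189 lower, 50.2% higher, against 41.7% with RLE factors, 39.2% with DESeq2 and 36.1% with no low-count filter.

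MDA-MB-231 WT cells raised NDRG1 from 19.2 ± 1.91 to 350 ± 45.3 CPM at 0.2% oxygen (log2 fold change 4.19 ± 0.12, n = 2 per group, adjusted p = 6.64e-08). CA9 rose from 12.3 ± 3.14 to 215 ± 20.9 CPM (4.12 ± 0.16, adjusted p = 3.76e-07). Of 26 other HIF targets 24 rose (median 1.35, adjusted p = 0.0376 with an estimated correlation), and of 21 HIF glycolysis genes 20 rose (median 0.84, adjusted p = 0.07 with an estimated correlation), by either count. The other HIF targets did not pass with the replicate as a block or without any 1 replicate of either genotype. Oxidative phosphorylation genes fell, 10 of 20, or 15 adjusted over the list alone (median -0.27, adjusted p = 0.502 with an estimated correlation). Of 18673 genes tested 1385 were higher and 1311 lower. The count of 2696 was 349 without WT hypoxia replicate 1, 380 and 411 without WT normoxia replicates 2 and 1, 4120 with no low-count filter and 5539 with the replicate as a block.

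In the MDA-MB-231 KO cells several genes went from silent to expressed or the reverse. WNT5A, a secreted WNT ligand, went from 0 reads in WT normoxia to 1329 in KO normoxia, and TMEM100, a membrane protein of BMP signalling, from 0 to 420. MBNL3, a splicing regulator of the muscleblind family, went from 3 reads to 6078, or 37.5 CPM. ZYG11A (chromosome 1, start 52842511, end 52894998) went from 2127 reads, 13.1 ± 0.78 CPM, to 0, and FAT3, an atypical cadherin, from 2330 to 0. Of 14 histone genes measured 12 rose by either count (median 2.14; H1-2 2.95), and of 17 mesenchymal and epithelial genes 11 rose and 3 fell (median 0.96; TGFBI 5.02), each with adjusted p = 0.395 with an estimated correlation. FOXA1, a pioneer transcription factor, fell from 1.89 to 0.0249 CPM in normoxia, and CA9 had a log2 fold change of -3.84 ± 0.13 (adjusted p = 4.2e-09).

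The KO raised 5604 genes and lowered 5458. Of 21 interferon response genes 10 fell and 3 rose by either count (median -0.17; IFI44 -2.46, OAS1 2.43), with adjusted p = 0.628 with an estimated correlation. No gene's hypoxia response was called different in KO cells by edgeR, with 1024 of 18673 at unadjusted p < 0.05. DESeq2 called 13, edgeR with no low-count filter 123, and edgeR with the replicate block 18. Leaving out 1 library gave 0 to 3, the 3 without KO normoxia replicate 2.

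HCT116 scramble ASO cells raised ANGPTL4 from 59.6 ± 0.419 to 741 ± 24.8 CPM at 0.2% oxygen (log2 fold change 3.64 ± 0.07, n = 2 per group, adjusted p = 8.03e-19). MT-ND2, a mitochondrially encoded subunit of complex I, fell from 2750 ± 213 to 686 ± 51.1 CPM (-2.00 ± 0.06). Cell cycle genes rose, 20 of 25 with 5 lower (median 1.22; MCM4 2.27), as did 20 of 20 sterol synthesis genes (median 1.53; MVD 2.89, INSIG1 2.78) and 20 of 20 ribosomal protein genes (median 1.22). All 21 HIF glycolysis genes rose (median 1.69) and all 13 mitochondrially encoded genes fell (median -2.56). Each of these lists had adjusted p = 0.334 with an estimated correlation, and the counts adjusted over the list alone were the same. In the stress response list 8 of 17 rose and 7 fell (median 0.08; SLC7A11 -3.51, CHAC1 -2.84), with adjusted p = 0.864 with an estimated correlation. Of 20157 genes tested 7108 were higher and 8157 lower, and the median over all genes was -0.12 with TMM and -0.06 with RLE factors.

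MALAT1 ASO in HCT116 raised DHRS2, a mitochondrial dicarbonyl reductase (chromosome 14, start 23630115, end 23645639), from 9.54 ± 0.197 to 53.8 ± 4.39 CPM in normoxia (log2 fold change 2.40 ± 0.05, n = 2 per group, adjusted p = 5.23e-16). AQP3, an aquaglyceroporin, rose from 9.75 to 19.9 CPM (1.25 ± 0.05, adjusted p = 1.69e-11). DNAH5, an axonemal dynein, fell by 1.07 ± 0.16 on the log2 scale (adjusted p = 0.000206). Of 13 MALAT1 neighbours on chromosome 11 measured 6 rose (median 0.11; NEAT1 0.54), and all 20 ribosomal protein genes fell (median -0.18), each with adjusted p = 0.288 with an estimated correlation, by either count. None of the 4 HCT116 line markers measured changed (median -0.07, adjusted p = 0.854 with an estimated correlation). Averaged over both conditions the ASO called 3940 genes, 1780 higher and 2160 lower. Of these 45.2% were higher, against 32.3% with DESeq2 and 62.8% with no low-count filter. In normoxia alone 581 genes were higher and 281 lower (67.4% higher), and under hypoxia alone 2401 were higher and 3355 lower (41.7% higher). The count of 3940 was 2482 without MALAT1 ASO normoxia replicate 1.

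In HCT116 the hypoxia response of the chemokine genes CXCL2 (interaction 5.77 ± 1.53, n = 2 per group, adjusted p = 0.0126), CXCL1 (5.75 ± 1.61, adjusted p = 0.0169) and CXCL3 (4.75 ± 0.73, adjusted p = 0.000268) was higher with the ASO. The sizes of these values depended on 1 of the scramble normoxia libraries. In that group CXCL1 stood at 25.8 ± 34.1, CXCL2 at 4.44 ± 5.29 and CXCL3 at 2.59 ± 2.32 CPM. Of 25 cell cycle genes 17 had a lower interaction, or 22 adjusted over the list alone (median -0.20, adjusted p = 0.537 with an estimated correlation). SRSF1 had an interaction of 0.27 (adjusted p = 0.0366). The interaction called 1440 genes higher and 2444 lower, 37.1% higher against 18.9% with DESeq2. The count of 3884 was 2562 without MALAT1 ASO normoxia replicate 2 and 2366 without MALAT1 ASO hypoxia replicate 1.

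**Figure D3:**
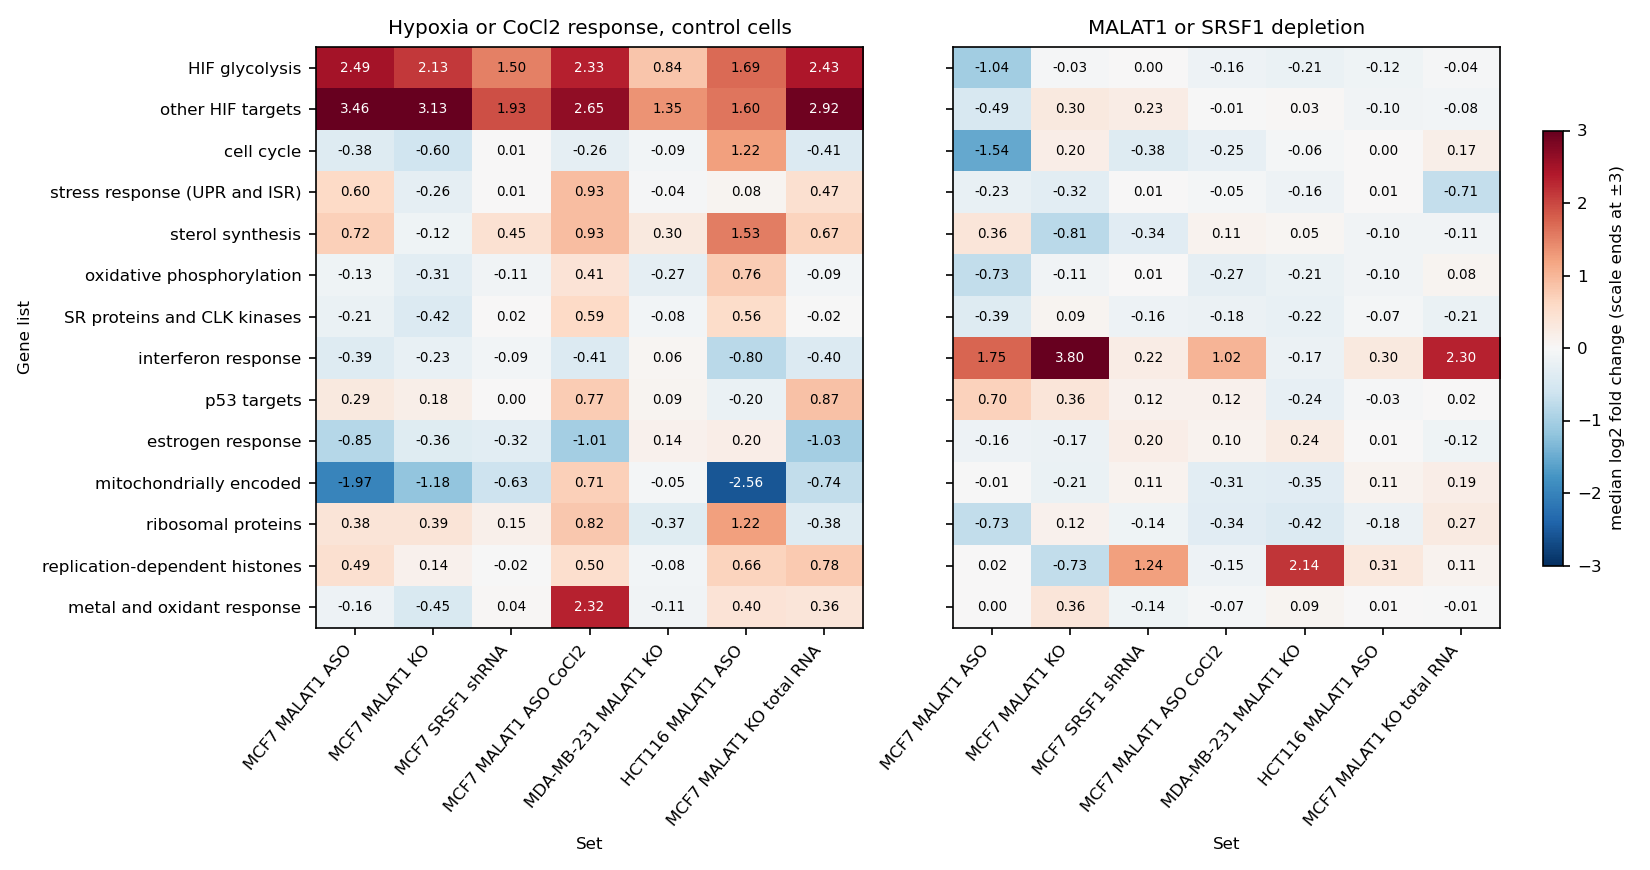
Median log2 fold change of each gene list (lines) in each of the 7 sets outside HEK293T (columns), for hypoxia or CoCl2 in control cells (left) and for depletion (right), on a colour scale that ends at 3. HIF lists are higher under treatment in every set, from 0.84 to 3.46, and the interferon list ranges from -0.17 in the MDA-MB-231 KO to 3.80 in the MCF7 KO.

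A common set of genes answered low oxygen in MCF7, MDA-MB-231 and HCT116 cells. In the 6 hypoxia sets read on the gene's own strand, 164 genes rose and 33 fell in every set, of 14006 tested in all, where independent lists would share 0.631 and 0.882. CA9 rose by 0.97 (HCT116) or more, NDRG1 by 1.91 to 5.40, ANGPTL4 by up to 6.24, PFKFB4 by 1.92 to 4.58, PDK1 by 1.53 to 4.28, and DDIT4, an mTORC1 inhibitor, by 1.64 to 5.42. BNIP3 rose by 1.55 to 3.92 and AMPD3, an AMP deaminase, by 0.84 to 4.97. Among the genes that fell, MT-ND2 ranged from -2.14 to -0.42, GPATCH4 from -2.23 to -0.45, COA7, an assembly factor of cytochrome oxidase, from -2.17 to -0.30, and SLC25A20, the carnitine carrier of mitochondria, from -3.36 to -0.25. With the HEK293T sets added, whose counts lie on the opposite strand, 39 were higher and 3 lower in all 8 sets. The count of 42 was 23 with DESeq2, 23 without MDA-MB-231 WT normoxia replicate 1 or WT hypoxia replicate 1, and 26 without WT normoxia replicate 2.

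**Figure D4:**
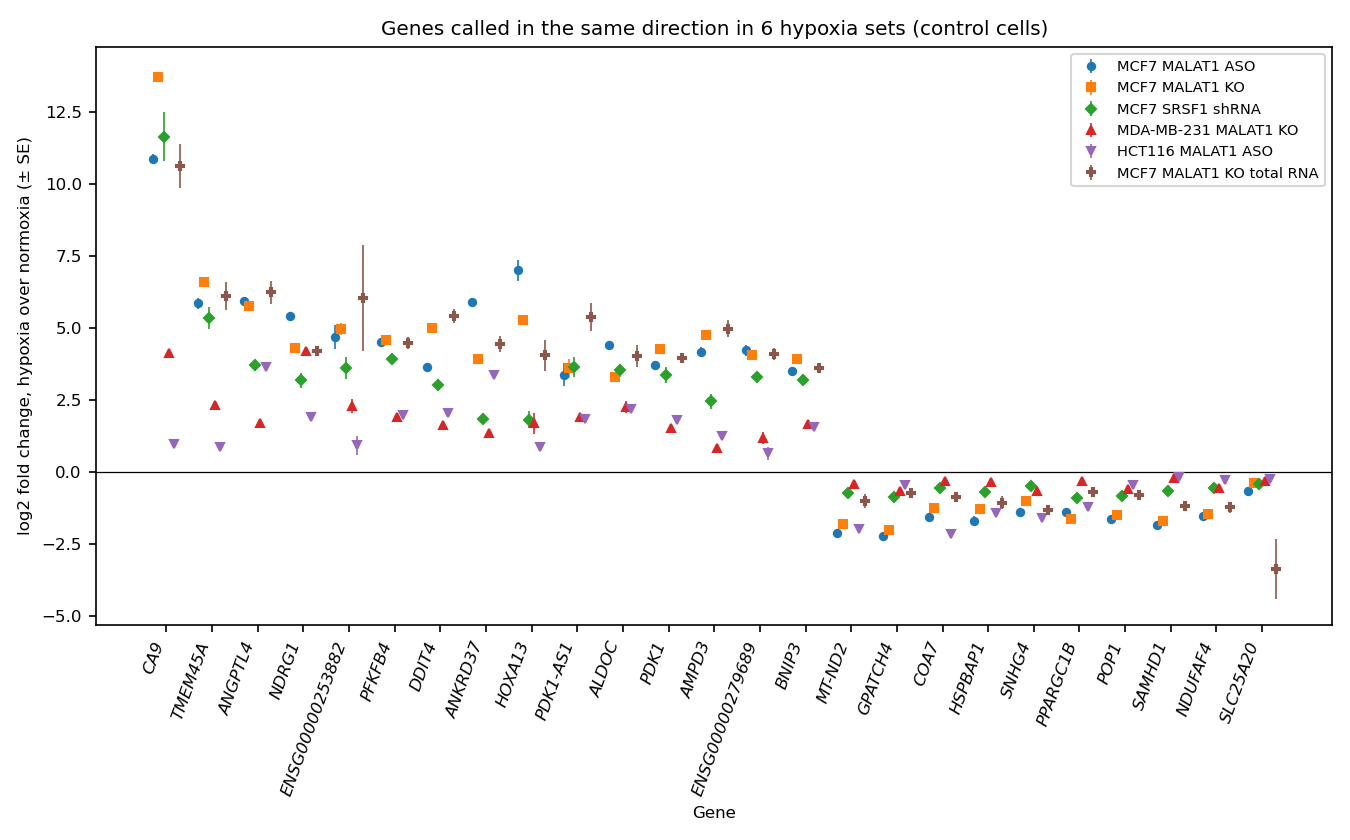
Log2 fold change of hypoxia over normoxia in control cells (points, with SE as bars) for the 25 genes picked from those called in the same direction in 6 hypoxia sets. NDRG1 lies between 1.91 and 5.40 in every set, and the highest CA9 points are fitted values of sets with 0 or 1 reads in normoxia, so they give no size.

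Across genes, the hypoxia changes of the MCF7 ASO and KO sets had a Spearman correlation of 0.79, and 96.3% of the 9672 genes called in both had the same sign. HCT116 differed, with 0 against the MCF7 ASO set (50.2% of 8528 genes with the same sign) and -0.23 against MDA-MB-231 (31.7% of 2211), though 0.42 against CoCl2 in MCF7 (68.4% of 10731). CoCl2 and the hypoxia of the MCF7 ASO set, both in scramble cells, shared 2741 higher and 3360 lower genes of 17984, where 1860 and 2240 would be shared by independent lists, with a correlation across genes of 0.32. The correlation of CoCl2 with hypoxia was 0.17 in the MCF7 KO set (57.6% with the same sign) and 0.14 in the MCF7 SRSF1 set (74.7% of 1599 genes). It was 0.09 in total RNA (54.3%) and -0.08 in MDA-MB-231 (52.1%). Genes are not independent replicates, so these correlations carry no p.

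MALAT1 depletion changed 1917 genes upward and 2474 downward in at least 3 of the 6 MALAT1 sets read on the gene's own strand, of 13999 tested, where independent lists would give 653 and 1200. As 4 of these sets are of MCF7 cells, MCF7 alone can reach 3 sets, and the numbers for independent lists leave out the shared line and knockout. With HEK293T added the numbers were 1909 and 2341 of 9461. In all 6 sets 36 genes rose and 96 fell. GDF15 rose by 0.27 to 5.24, OAS1, an interferon-induced antiviral enzyme, by 0.93 to 5.30, S100P, a calcium-binding protein, by 0.83 to 2.57 in the 5 polyA sets, and the long noncoding RNA PURPL by 0.92 to 3.71. FABP5, a fatty acid-binding protein, ranged from -6.63 to -0.19 and TTLL7, a tubulin polyglutamylase, from -4.67 to -0.22. SLC18B1, a vesicular polyamine transporter, fell as well, from 1.36 to 0.00459 CPM in the MCF7 KO in normoxia. Across genes the ASO effects in the MCF7 sets correlated at 0.62, those of ASO and KO in MCF7 at 0.02 to 0.13, and those of the MCF7 and MDA-MB-231 KO at -0.01. The ASO effect in HCT116 correlated at 0.24 with the MCF7 ASO set and at 0.33 with the CoCl2 set. The MCF7 KO effects in polyA and total RNA correlated at 0.47. SRSF1 shRNA moved 505 genes up and 506 down in both MCF7 and HEK293T, of 9888, where 468 and 536 would be shared by independent lists. The count of 1011 was 632 with DESeq2, and the HEK293T part was read on the opposite strand.

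Calls of the HEK293T sets, read on the opposite strand, counted toward the core hypoxia genes, those that rose in at least 5 of the other hypoxia sets. These core genes tested whether depletion altered the common response. In the MCF7 ASO set their median rise was 1.40 in scramble and 0.75 in MALAT1 ASO cells, with 260 of 347 genes lower and 3 higher (median interaction -0.66, camera p = 0.00113 with an estimated correlation, adjusted p = 0.0102 over the 9 sets). In the MCF7 KO set it was 1.27 in WT and 1.30 in KO cells (median interaction 0.08, 142 genes higher and 85 lower, adjusted p = 0.0922 with an estimated correlation). SRSF1 shRNA cells had 0.61 against 0.45 (0.12, adjusted p = 0.0922 with an estimated correlation), without the replicate block for its paired libraries. Under CoCl2 ASO cells had 0.60 against 0.80 (-0.19, 357 of 849 genes lower and 58 higher, adjusted p = 0.0922 with an estimated correlation). MDA-MB-231 gave 0.02, HCT116 0.03 and total RNA -0.07, with adjusted p of 0.565, 0.565 and 0.139 with an estimated correlation. HCT116's value was -0.01 with RLE factors, with no low-count filter, and without MALAT1 ASO normoxia replicate 1.

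**Figure D5:**
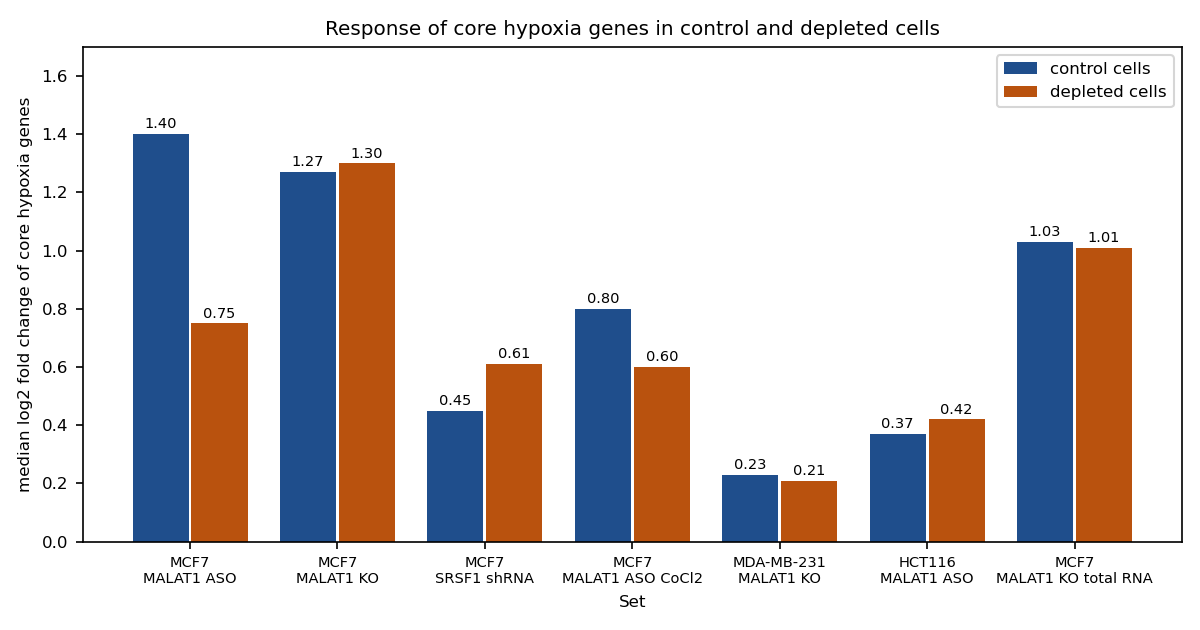
Median log2 fold change of core hypoxia genes in control cells (blue bars) and depleted cells (orange bars) of the 7 sets outside HEK293T, with CoCl2 as the treatment in the CoCl2 set. The largest difference is in the MCF7 ASO set, 1.40 against 0.75.

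A joint fit of the MCF7 ASO and KO sets, added after the data were seen, tested whether the interactions themselves differed between both ways of depletion. Core hypoxia genes common to both lists had a lower interaction with the ASO than with the KO, 228 of 338 lower and 19 higher (median difference -0.69, adjusted p = 1.2e-05 with an estimated correlation). HIF glycolysis genes differed by a median of -1.09 (18 of 21 lower, adjusted p = 0.000278 with an estimated correlation) and other HIF targets by -1.69 (23 of 26 lower and 1 higher, adjusted p = 0.000227 with an estimated correlation). Mitochondrially encoded genes differed the other way, all 13 of 13 (median 2.07, adjusted p = 0.00127 with an estimated correlation). Interferon response genes (median -0.56, adjusted p = 0.613 with an estimated correlation) and cell cycle genes (-0.33, adjusted p = 0.32 with an estimated correlation) did not pass. Sets and ways of depletion cannot be told apart in this comparison, as each way has its own set and control.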

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

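The oligonucleotide and every-line tests of the interferon pattern, the limit to MCF7 and HCT116 cells and the split by starting state in the MDA-MB-231 pattern, both strand tests of HEK293T and the joint fit of the MCF7 ASO and KO sets were chosen only after the result was seen. Every value in the following 4 paragraphs was picked out because a test of the difference, the interaction, found the treatment response of depleted and control cells to differ.

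By set, the interaction called 4970 genes in the MCF7 ASO set, 8302 in the MCF7 KO set, 2207 and 2450 in the HEK293T MALAT1 and SRSF1 sets, 4393 in the CoCl2 set, 3884 in HCT116 and 65 in total RNA. The median interaction of core hypoxia genes was -0.66 in the MCF7 ASO set, 0.08 in the KO set, 0.12 in the MCF7 SRSF1 set and -0.19 in the CoCl2 set, by unadjusted camera p.

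In the MCF7 ASO set the interaction was -0.64 for MALAT1, 0.58 for SRSF1, 3.78 for CXCL1, 3.26 for SGK1 and 2.81 for ENSG00000287448, which had 1 read in scramble hypoxia. It was -5.39 for LINC03047, which had 1 read in scramble normoxia, -5.15 for HOXA13 and -4.56 for ADM. HOXA13 had 4 reads in scramble normoxia, and CXCL1 had 10 there and 4 in scramble hypoxia. The ASO set's lists were HIF glycolysis (-0.75) and other HIF targets (-1.22). In the MCF7 KO set the interaction was -0.72 for MALAT1, -0.35 for SRSF1, 2.53 for LYPD1, -4.70 for MT-TA, -3.90 for MT-TP and -3.47 for MT-TT. HOXA13 had 2.50, resting on 3 reads in KO normoxia, and TMSB4XP8 had 4.40, with 5.23 ± 6.91 CPM in WT normoxia, a pseudogene read from mainly 1 library. The KO set's lists were other HIF targets (0.60), nuclear speckle and paraspeckle (0.23), estrogen response (-0.34), p53 targets (0.29), mitochondrially encoded (-1.07) and MCF7 line markers (-0.57).

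In the CoCl2 set the interaction was 0.20 for SRSF1, 1.97 for LSMEM2, 1.83 for RASD2, 1.76 for DNAH17-AS1, -3.04 for KRT16 and -2.56 for TNF, and -6.52 for the pseudogene RPL22P1, whose scramble CoCl2 group stood at 3.92 ± 3.05 CPM. In HCT116 it was 0.27 for SRSF1, 5.77 for CXCL2, 5.75 for CXCL1 and 4.75 for CXCL3, and -2.81, -2.54 and -2.34 for the processed pseudogenes RPL17P39, ENSG00000185641 and RPS18P5, whose reads cannot be placed with certainty.

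In total RNA the interaction was 3.19 for PGM1, 2.03 for DKK1, -2.21 for LINC02762 and -1.97 for both ENSG00000286379 and ENSG00000275846. MEG8 had a fitted 12.77 that gives no size, since its groups held 285, 0, 0 and 3 reads. The joint fit of the MCF7 ASO and KO sets was a test of the difference between interactions, with -0.69 for core hypoxia genes, -1.09 for HIF glycolysis, -1.69 for other HIF targets and 2.07 for mitochondrially encoded genes.

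Most interferon response genes were called higher in MALAT1-depleted MCF7 cells of the ASO, CoCl2 and KO sets, though the list did not pass there (adjusted p = 0.247, 0.259 and 0.333 with an estimated correlation). In total RNA of MCF7 KO cells most members were called higher too, and the list passed, though not without some single replicates. An introduced oligonucleotide cannot account for the rise in the KO set, which had none and held a median of 3.80. That rise is part of the pattern itself and was seen before the test was chosen, so the test decides nothing further. In the ASO and CoCl2 sets the controls had an oligonucleotide too, the scramble ASO. An effect particular to the MALAT1 ASO, apart from loss of MALAT1, remains open there, as the KO set has its own cells and control. The rise was not alike in every line. In the MDA-MB-231 KO 10 of 21 members were lower and 3 higher by either count (adjusted p = 0.628 with an estimated correlation). In HCT116 7 of 18 were higher, or 8 adjusted over the list alone, and none lower (adjusted p = 0.291 with an estimated correlation). An effect of MALAT1 loss shared by every line cannot be excluded by this, since differences between cultures or clones could hide it in MDA-MB-231. Differences between cultures or clones apart from MALAT1 remain open. The list's mean level already spanned 2.60 log2 CPM among untreated control MCF7 cells, from 0.60 in the KO set to 3.20 in the ASO set. Controls of the ASO and CoCl2 sets (3.20 and 1.35) had received a scramble ASO, so treatment and culture cannot be told apart in this span.

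In MDA-MB-231, 25 genes stood at 0 to 3 reads in 1 genotype and above 1 CPM in every library of the other, 9 off and 16 on in the KO. Libraries of MCF7 or HCT116 cells can be excluded, since the KO mean correlated across genes at 0.926 with its own WT and at most at 0.845 with these lines, HEK293T not being compared. Of the 11 genes that start alike in MCF7 WT 0 switched alike in its KO (95% upper bound 28.5%, taking genes as independent). This argues against a full switch of most of them by loss of MALAT1 in both KO lines. A weaker shared effect, or one hidden by differences between clones, was not tested. Loss of MALAT1 remains open for the 14 that start otherwise, with 26.9% of MALAT1 left in this KO and 2.76% in MCF7. Differences between clones or sublines remain a candidate explanation that the test left open. The antisense set with most such genes held 4, with a Poisson interval of 1.09 to 10.2 around the limit of 2.50. The MCF7 KO held 3 such genes in polyA RNA, 3 off and 0 on, and 8 in total RNA, 6 off and 2 on.

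In the HEK293T sets abundant genes were near 0 while their antisense genes were high. Reads counted on the strand opposite to the gene fit this, with at least 38.33% of reads in antisense-type genes. Reads that carry no strand, such as DNA or an unstranded library, can be excluded, since TUBA1B-AS1 exceeded TUBA1B by at least 417 times.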

How the results depend on the processing

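No test was chosen for this part after a result was seen, except for the own-strand sets, the gene lists under other settings and the joint fit. With 2 libraries per group, leaving out a library leaves a lone library whose spread is taken from the other groups, and total RNA with its 12.3 to 18.2 depth in units of 1e+06 found few interactions in simulations (2.99% at 1.5-fold). Of the summary results, RLE factors kept 38 of 41, no low-count filter 33 of 41, DESeq2 21 of 31, the replicate block 22 of 29 and leaving out a library 413 of 468. Of 360 values for named genes, DESeq2 kept 340 of 356 (12 weaker, 4 stronger), RLE factors 355, no low-count filter 356 and the block 354. Leaving out a library kept 2918 of 3108 and weakened 170. Replicate numbers paired libraries in the MCF7 SRSF1 set. In MDA-MB-231 the correlations by number were -0.05 to 0.59, and the other sets had -0.19 to 0.18. Except where named, the cause was not tested.

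Core hypoxia genes of the MCF7 KO set lost their unadjusted call with RLE factors (0.09), no low-count filter (0.07), the replicate block (0.08), a core list from 3 sets (0.04), the own-strand core list (0.06) and without most single libraries (range 0.07 to 0.10). The MCF7 SRSF1 set lost it without most single libraries (0.10 to 0.19). The CoCl2 set lost it with the replicate block (-0.19) and without some single libraries (-0.23 to -0.17). The HEK293T MALAT1 set gained it with the preset correlation (-0.13) and without some single libraries (-0.16 to -0.06). The HEK293T SRSF1 set gained it with RLE factors (-0.19), the preset correlation (-0.19) and without some single libraries (-0.24 to -0.12). Counts of both HEK293T sets lie on the opposite strand, so their values are mostly not those of the core genes themselves. MDA-MB-231 ran from 0.02 to 0.06, passing without WT normoxia replicate 1. HCT116 turned to -0.01 with RLE factors, with no low-count filter and without MALAT1 ASO normoxia replicate 1, and passed with the preset correlation (0.03) and without MALAT1 ASO normoxia replicate 2 (range -0.01 to 0.07). Total RNA passed with the preset correlation (-0.07), with the own-strand core list (-0.09) and without WT hypoxia replicate 1, and stood at 0 without WT hypoxia replicate 3 (range -0.09 to 0).

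Of all lists and contrasts 18 lists were called, 38 with no low-count filter, 7 with the replicate block, 193 with the preset correlation, and 2 to 6 without a replicate. The 6 lists of the MCF7 KO interaction were 0 with RLE factors, with the block and without any 1 replicate. Of the 18, only both HIF lists of total RNA's hypoxia response passed in every setting. Genes called alike in every hypoxia set numbered 42, 23 with DESeq2, 23 to 44 without a library and 197 in own-strand sets. SRSF1 depletion in both lines called 632 with DESeq2.

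Hypoxia in the MCF7 SRSF1 set called 1898 genes, 3142 with no low-count filter, 6166 with the replicate block, and 421 to 1474 without a library. Its interaction called 3 with DESeq2, 61 with no low-count filter and 414 with the block. The HEK293T MALAT1 set called 3776, 2641 and 1315 with DESeq2, and the HEK293T SRSF1 set 3312 and 1480. MDA-MB-231 hypoxia called 4120 with no low-count filter, 5539 with the replicate block, and 349 to 4038 without a library. Its interaction called 13 with DESeq2, 123 with no low-count filter, 18 with the block, and 0 to 3 without a library. Without a library HCT116 called 2482 to 3934 for the ASO and 2366 to 4135 for the interaction. Total RNA's interaction called 296 with DESeq2, 445 with no low-count filter, and 17 to 1656 without a library.

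On leaving out a library, MALAT1 and SRSF1 changed sign only in values that had not passed. In the MCF7 SRSF1 set the hypoxia change of MALAT1 ran from 0 to 0.46, that of SRSF1 from -0.24 to 0.02 (0.01 between), and the interaction of MALAT1 from -0.02 to 0.44. In MDA-MB-231 the hypoxia change of MALAT1 ran from -0.17 to 0.02, its interaction from -0.03 to 0.17, and the interaction of SRSF1 from 0 to 0.21. SRSF1 with the ASO in HCT116 ran from -0.10 to 0.02 (0 between), and the interaction of MALAT1 in total RNA from -0.16 to 0.09 (0.04 and 0.07 between).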

Other observations

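Members of further lists were called, though none of these lists passed with an estimated correlation. In the MALAT1 KO total RNA, SR proteins and CLK kinases fell in 10 of 17 cases with 1 higher, or 12 and 1 adjusted over the list alone (median -0.21, adjusted p = 0.232 with an estimated correlation). With MALAT1 ASO in MCF7 15 of 17 fell and 2 rose (median -0.39, adjusted p = 0.149 with an estimated correlation), while in the MCF7 KO 11 rose and 4 fell (median 0.09, adjusted p = 0.338 with an estimated correlation). Ribosomal protein genes all fell with MALAT1 ASO, 20 of 20 in the MCF7 hypoxia set (median -0.73, adjusted p = 0.0974 with an estimated correlation) and 20 of 20 in the CoCl2 set (median -0.34, adjusted p = 0.259 with an estimated correlation). In MCF7 WT total RNA, histone genes rose under hypoxia in 13 of 16 cases (median 0.78, adjusted p = 0.249 with an estimated correlation), and 14 of 20 estrogen response genes fell with 1 higher (median -1.03, adjusted p = 0.083 with an estimated correlation).

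In MDA-MB-231 KO cells 3 of 8 MDA-MB-231 line markers were higher and 2 lower (median 0.10, adjusted p = 0.734 with an estimated correlation). Of the 6 MCF7 line markers measured in them 5 rose (median 1.12, adjusted p = 0.426 with an estimated correlation). ADM, a HIF target, had a depletion effect of -1.86 ± 0.05 there.

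No split test was chosen after its result, except for the division of the interaction's splits by equal numbers. The libraries of each condition were split in other ways to see how many genes other splits would call. In the sets with 2 libraries per group the 18 splits are too few to test this, and only the real split, 1 of 18, reached the real count. The highest other counts, against 14546, 13953, 7744, 4268, 7036, 8970, 11062 and 3940, were 4970, 8302, 8, 2207, 2450, 4393, 0 and 3884, in the order of sets used in the methods. In 6 of these sets the highest other split swapped the arms in 1 condition, so its count is that of the interaction and not a count by chance. In total RNA 60 splits were used, the real one and others drawn at random. Of these 60 splits 1, the real one, reached the 5282 genes of the depletion effect, the highest other giving 126. A random grouping of these libraries is thus unlikely to reach that count, though chance differences between cultures were not tested. For the interaction in total RNA 4 of 60 splits reached 65 genes, the highest other giving 952. The other 3 put unequal numbers of KO libraries in an arm of each condition, so the depletion effect entered their counts and the test decides nothing. For its hypoxia response the 10 splits are too few, with 6718 genes in the real one and 0 in the highest other.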
